A study of Mus musculus with 24 samples.

How the data were processed

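RNA sequencing libraries of mouse bone marrow-derived macrophages in 8 groups of 3 were used, 24 in all. The files deposited by the authors hold raw read counts per Ensembl gene identifier, in a file for each library, without a header or normalization. Per the submitters' processing notes the tools were STAR, featureCounts, DESeq2 and deepTools and the genome build was GRCm38, with no versions. Their annotation release, strand setting, treatment of reads with several alignments and filters were not given in the sources used here. Per the labels, libraries were made with a stranded mRNA kit and sequenced on a HiSeq instrument. That the values are counts was checked on the files, which hold whole numbers with totals from 4181890 to 8122945. Each file held 43629 gene identifiers, of which 42462 were matched to gene names and positions of GENCODE M21.

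Groups were taken from the labels by stimulus and time, and the replicate number was not used as a block, since the labels do not say that it pairs libraries. The groups, comparisons, tests, alternatives and the rule for named genes were set before the data were examined. Genes were kept with filterByExpr by group (minimum count 10), which left 12765 tested and 30864 not tested. Counts were scaled by TMM and fitted with edgeR 4.0.16 under R 4.3.3, with all 8 groups in the model and a term for each group. Quasi-likelihood tests gave p-values, two-sided, which were adjusted by Benjamini-Hochberg over the tested genes, and a gene was called at an adjusted p below 0.05. There were 9 comparisons of groups: each stimulus against unstimulated cells at each time, LPS with IFNg against LPS at each time, and unstimulated cells at 18 h against 1 h. Another 3 tests compared the response at 18 h with that at 1 h by an interaction contrast. The common biological coefficient of variation was 0.0736.

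Gene lists were written before the data were examined, 36 in number. Each was tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. Which of the lists are described for each comparison was chosen after their results were seen, and fry from limma was run beside camera; it tests whether the genes of a list move one way and does not compare them with other genes. For each list the members were also counted with p-values adjusted over the list alone.

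Genes were named by a rule with 3 parts. The first took the 8 genes with the largest fitted increase and the 6 with the largest decrease in each comparison of groups. It was limited to called genes with a mean of at least 5 CPM over the 6 libraries and no overlap between the libraries of the groups, and it left out symbols of predicted genes and genes with no symbol. Up to 4 called members of each described list with the largest change made up the next part. The last part held a fixed set of NAD+, damage, oxidant, metabolic and polarization genes, open to naming whether called or not, and not all were named in each comparison. A few genes that the rule names are not reported here. For a gene with no counts in a group of 3 libraries the fold is a lower bound against 3 counts over that group, and with 1 to 3 counts it is a ratio with an exact 95% interval.

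The fit was tested on counts simulated with the means of unstimulated libraries and the library sizes and gene dispersions of these data. Few genes were given a known change, so scaling under broad shifts was not tested. For LPS at 1 h, 51 of 67 genes with a 1.5-fold change, 64 of 67 with 2-fold and 66 of 66 with 4-fold were called. Of 191 calls 10 were false. For the LPS interaction 22 of 67, 60 of 67 and 66 of 66 were called, with 4 of 152 calls false.

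Alternatives were median-of-ratios or library-size scaling, no filter on low counts, DESeq2 1.42.0, limma-voom, fits on the compared groups alone, a replicate block, an adjusted p threshold of 0.01, and each replicate left out in turn. A pair of alternatives was chosen after seeing the data, leaving out LPS 18 h replicate 2 with IL-4 18 h replicate 2, and unstimulated 18 h replicate 3 with IL-4 18 h replicate 3. Calls were also counted over other splits of the same libraries, and for the interactions the number of splits was raised to 100 after a smaller draw had been seen. Explanations weighed for 3 patterns had the outcomes for and against them written before the tests were run. For the ratio of receptor reads, the demand that its interval lie under the bound as well was added after the ratio was seen. Reads of the 30864 untested genes were used only to compare libraries.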

Results

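Gene expression was measured by RNA sequencing in macrophages grown for 7 days from the bone marrow of wild-type C57BL/6 mice in 20 ng/mL CSF-1, the growth factor of this lineage. The cells were left unstimulated or received bacterial lipopolysaccharide (LPS, the ligand of TLR4), LPS with 50 ng/mL interferon gamma (IFNg), or 20 ng/mL interleukin 4 (IL-4). Cells were taken after 1 h or 18 h, which gave 8 groups of 3 libraries and 24 libraries in all. The labels give the LPS dose as 20 or 100 ng/mL without saying which was used where. Total counts per library ran from 4181890 to 8122945, and 15450 to 19108 genes had at least 1 read. Of the 43629 gene identifiers in each file, 12765 passed the count filter and were tested. At this depth a gene with no counts in a group could lie at up to 0.132 to 0.224 CPM (counts scaled to the library total) in it, by a floor of 3 counts over the group. Intervals and floors cover counting error only. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

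The first principal component held 60.1% of the variance and set the 18 h LPS groups apart from the rest, and the second held 17.4% and set the 1 h LPS groups apart. The question behind the series was how inflammatory macrophages use NAD+ and respond to oxidants and DNA damage, so genes of these pathways were followed in each comparison beside stimulus markers. Values after gene names are log2 fold changes ± SE, with 3 libraries in each group, from edgeR quasi-likelihood fits with Benjamini-Hochberg adjusted p. For a gene with no counts in a group the fold is a lower bound, and with 1 to 3 counts it is the ratio of depth-scaled counts with its 95% counting interval. List tests are camera with a preset correlation, followed by the adjusted p with an estimated correlation where marked estimated, and list medians count members with a group at 0 at their bound. All changes are relative to TMM scaling, which sets the bulk of tested genes to no change. Several named genes overlap genes on the opposite strand, such as Il1b, Il1a, Cdkn1a, Cd38, Csf2, Mt2, Slc7a11, Hk2, Pfkfb3, Rpl10a, Art3, Cxcl10 and Cxcl11. Whether reads were counted by strand was not given.

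**Figure D1:**
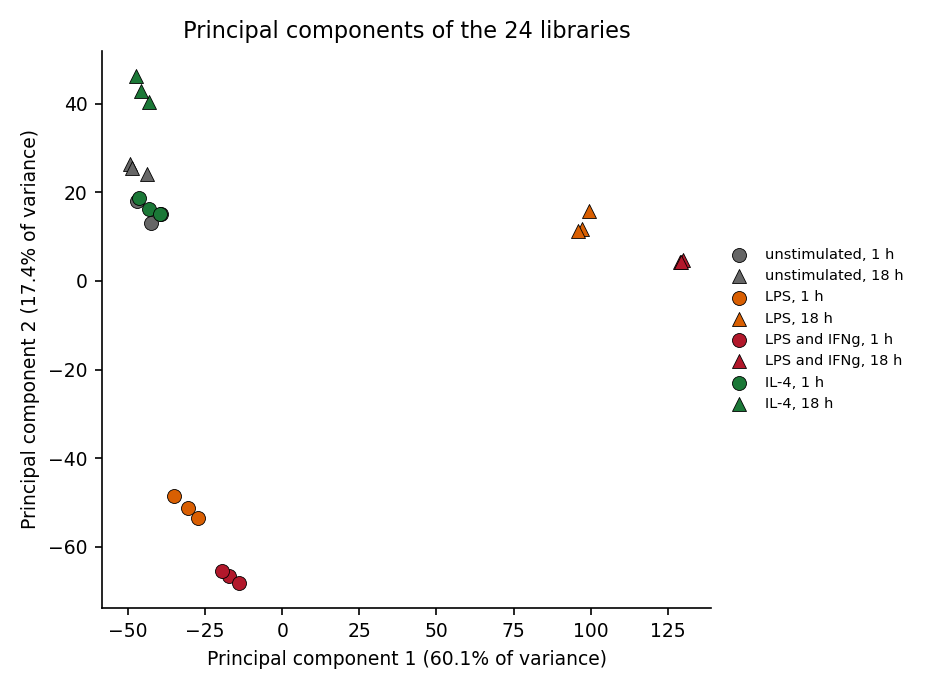
Each point is a library, placed by the first and second principal components of log2 CPM of the 12765 tested genes, with the percent of variance on each axis; colours are stimuli, circles 1 h and triangles 18 h. The 18 h LPS and LPS with IFNg libraries lie apart along the first component, which holds 60.1% of the variance.

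The comparison of LPS with unstimulated cells at 1 h asked which transcripts answer first to a bacterial signal. Il1b (10.05 ± 0.29) and Il1a (9.99 ± 0.20) of the interleukin-1 cytokines, the neutrophil attractant genes Cxcl1 (9.96 ± 0.23) and Cxcl2 (8.73 ± 0.14), and Csf2 (at least 119-fold higher) rose. Plat, the tissue plasminogen activator (889.7-fold higher in counts, 95% interval 159 to 35200), Sele, the endothelial adhesion molecule E-selectin (688-fold higher in counts, 95% interval 123 to 27240), and Tnfsf4, the ligand of OX40 (525-fold higher in counts, 95% interval 145 to 4346), rose as well. Tnf, encoding tumour necrosis factor, rose from 34.6 ± 7.59 to 4929 ± 110.1 CPM (mean ± SD, n = 3), a log2 change of 7.14 ± 0.13. The genes that fell most were Ier5l (-4.58 ± 0.23), Dusp6, a phosphatase of ERK kinases (-2.43 ± 0.12), the small GTPase gene Rhov (-2.40 ± 0.17), Thbd, encoding thrombomodulin (-2.39 ± 0.24), and the zinc finger genes Zfp157 (-2.77 ± 0.27) and Zfp329 (-2.43 ± 0.32). For each of these genes the adjusted p was 6.5e-07 or smaller.

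Of the inflammatory cytokine and chemokine list, 25 of 26 measured members rose and none fell (median 4.95, adjusted p = 5.6e-44), with the same count adjusted over the list alone. All 19 members of the list of NF-kappaB feedback genes rose, on both adjustments, including Nfkbiz (7.70 ± 0.13), Tnfaip3, which encodes the inhibitor A20 (5.62 ± 0.10), and the costimulatory receptor gene Cd40 (5.11 ± 0.15); its adjusted p was 3.7e-40. Among immediate early genes, 18 of 22 rose and none fell (19 adjusted over the list alone), with Ier3 (4.34 ± 0.18), Dusp2 (3.90 ± 0.12) and Dusp1 (3.22 ± 0.08) ahead (adjusted p = 3.9e-18). Of the itaconate and arginine metabolism list, 5 of 13 members rose on both adjustments (adjusted p = 0.0034); Acod1, the enzyme that makes itaconate, was 7.56 ± 0.21, and scaling by library size alone put the list at 5 higher and 2 lower. Of the type I interferon response list, 10 of 30 rose and 2 fell on both adjustments, with Ifnb1, encoding interferon beta (503-fold higher in counts, 95% interval 89.7 to 19920), Oasl1 (3.99 ± 0.24) and Ifit1 (3.26 ± 0.21) at the top. This list had adjusted p = 0.0011 (0.74 estimated).

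Nampt, the rate-limiting enzyme of NAD+ salvage (gene ENSMUSG00000020572, chromosome 12, 32819545 to 32853349, GRCm38), went from 99.3 ± 10.7 to 126 ± 8.15 CPM (0.35 ± 0.07, adjusted p = 5.5e-04); scaled by library size alone it was 0.16 and no longer called (adjusted p = 0.0736, the highest over its alternatives, which began at 8.2e-06). On the NAD+ salvage and synthesis list, 2 of 9 measured members rose on both adjustments (adjusted p = 0.37), and 0 rose with library-size scaling, which put the median at -0.02; Nadk (0.22 ± 0.07) also lost its call without LPS 1 h replicate 3 or unstimulated 1 h replicate 2, or with no filter (adjusted p from 0.0049 to 0.763 over its alternatives). Among p53 targets and DNA damage response genes, 9 of 27 rose and 5 fell (10 and 5 adjusted over the list alone). These included Gadd45b, a stress sensor (3.32 ± 0.09), the antiproliferative gene Btg2 (2.65 ± 0.10), the death receptor gene Fas (2.38 ± 0.28), Cdkn1a, encoding the cell cycle inhibitor p21 (2.23 ± 0.09), and Mdm2, the ligase that degrades p53 (1.52 ± 0.08). The list's median was -0.02, its mean 0.42, and its test pointed up without a call (adjusted p = 0.071), but was called with library-size scaling (0.028; 0.028 to 0.38 over the camera alternatives). Of the antioxidant and NRF2 target list, 7 of 26 rose and 1 fell on both adjustments, among them the cystine transporter gene Slc7a11 (2.96 ± 0.14), the mitochondrial superoxide dismutase gene Sod2 (2.90 ± 0.10) and the metallothionein gene Mt2 (2.49 ± 0.15). The antioxidant list had adjusted p = 0.0055 (0.74 estimated), and library-size scaling turned the median to -0.11 with 6 higher and 6 lower. Of the NADPH oxidase list, 4 of 9 rose and 1 fell on both adjustments (adjusted p = 0.19), including the oxidase gene Nox1 (1.48 ± 0.28), Cybb, the catalytic subunit of the phagocyte oxidase (0.86 ± 0.08), and the chaperone gene Cybc1 (-0.56 ± 0.08); library-size scaling gave 3 and 3 and a median of -0.07. Parp1, the main DNA break sensor among poly(ADP-ribose) polymerases (-0.10 ± 0.08), the heme oxygenase gene Hmox1 (-0.11 ± 0.07) and the NAD+ synthesis gene Nmnat1 (0.20 ± 0.18) were not called.

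In all, 2837 of 12765 genes were called, 1376 higher and 1461 lower, of which 541 and 385 changed at least 2-fold. With scaling by library size alone, which moved the median of all genes by -0.19, 4443 genes were called, 895 higher and 3548 lower.

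The comparison of LPS with unstimulated cells at 18 h asked what the later response to LPS holds. Saa3, an acute-phase protein of macrophages (13.43 ± 0.33), Ccl5, a chemokine (10.90 ± 0.18), Acod1 (10.73 ± 0.22), Nos2, the inducible nitric oxide synthase (10.37 ± 0.22), Slfn4, an interferon-induced gene (10.21 ± 0.18), Cxcl3, a neutrophil attractant (at least 407-fold higher), the complement factor gene Cfb (at least 169.6-fold higher) and U90926 (at least 344-fold higher) rose most. Il1b (9.99 ± 0.32), Tnf (2.73 ± 0.13), the interferon-induced chemokine gene Cxcl9 (8.98 ± 0.30) and Arg1, encoding arginase 1 (8.45 ± 0.23), were higher too. Kif14, a mitotic motor (at least 140.4-fold lower), Esco2, which acts in sister chromatid cohesion (at least 96.5-fold lower), Ankle1, a nuclease gene (at least 78.3-fold lower), Nptx1 (762-fold lower in counts, 95% interval 260.4 to 3696), the centromere protein gene Cenpf (873-fold lower in counts, 95% interval 156 to 34510) and Pimreg, a mitotic regulator (716-fold lower in counts, 95% interval 128 to 28300), fell most. The proliferation marker Mki67 fell from 354 ± 41.9 to 9.39 ± 2.94 CPM (-5.22 ± 0.20). For each of these genes the adjusted p was 1.7e-13 or smaller.

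Nampt rose 3.62-fold, from 99.9 ± 1.23 to 362 ± 7.5 CPM (1.86 ± 0.07), and the NAD+ kinase gene Nadk rose (1.04 ± 0.07). Of the salvage and synthesis list, 5 of 9 rose and 1 fell on both adjustments (adjusted p = 0.098), while library-size scaling gave 2 and 2 and a median of -0.07; the lower gene, Nadk2, lost its call without LPS 18 h replicate 1 or 2 or unstimulated 18 h replicate 1. Nmnat1 was 0.48 ± 0.18 (adjusted p = 0.018) and lost its call without LPS 18 h replicate 2 (0.41, adjusted p = 0.0716) or unstimulated 18 h replicate 3 (0.34, adjusted p = 0.114), with library-size scaling (0.06) and with DESeq2 (0.48). Over its alternatives the adjusted p of Nmnat1 ran from 0.0099 to 0.75. Cd38, the NAD+ hydrolase (ENSMUSG00000029084, chromosome 5, 43868553 to 43912375), went from 0.42 ± 0.233 to 164 ± 6.49 CPM (8.54 ± 0.24), and its relative Bst1 rose (5.28 ± 0.12). Of the list of NAD+ hydrolases and sirtuins, 6 of 9 rose and 0 fell on both adjustments. The hydrolase and sirtuin list had adjusted p = 0.022 (0.061 estimated). In the PARP family 12 of 17 rose and 2 fell on both adjustments, with Parp14 (3.12 ± 0.13), Parp11 (3.12 ± 0.09), Parp10 (3.04 ± 0.11) and Parp12 (2.62 ± 0.07) ahead. The PARP list had adjusted p = 5.2e-04 (0.18 estimated). Parp1 (ENSMUSG00000026496, chromosome 1, 180568924 to 180601254) fell (-1.47 ± 0.09).

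Repair and damage genes moved as follows. Of the double-strand break repair list, 25 of 34 fell and 2 rose (26 and 2 adjusted over the list alone; adjusted p = 4.3e-06), led by the nuclease gene Exo1 (-5.91 ± 0.31), the Fanconi gene Fancd2 (-5.78 ± 0.36) and the checkpoint kinase gene Chek1 (-5.21 ± 0.38). Of the base excision and single-strand break repair list, 13 of 24 fell and 4 rose on both adjustments, with Neil3, a glycosylase (285-fold lower in counts, 95% interval 50.7 to 11270), Pole, a DNA polymerase subunit (-5.81 ± 0.27), and Lig1, a DNA ligase (-3.68 ± 0.16), among the lower. The base excision list had adjusted p = 0.022 (0.18 estimated) and 0.073 with library-size scaling (0.017 to 0.18 over the camera alternatives). Among p53 targets, 15 of 27 rose and 6 fell on both adjustments, with Fas (2.54 ± 0.22), the damage sensor gene Ddb2 (2.31 ± 0.08) and Mdm2 (1.81 ± 0.09) higher and Sesn1 (-2.21 ± 0.10) lower. The p53 target list had adjusted p = 0.022 (0.13 estimated). Cdkn1a (1.79 ± 0.09) and Gadd45b (1.67 ± 0.11) rose. All 25 S phase genes and all 24 G2 and mitosis genes fell on both adjustments, such as the ribonucleotide reductase gene Rrm2 (-6.71 ± 0.23), Uhrf1 (-6.01 ± 0.24), the cyclin gene Ccnb2 (-7.68 ± 0.34) and Foxm1 (-7.46 ± 0.34). The adjusted p was 9.8e-16 for the S phase list, with adjusted p = 0.057 with an estimated correlation, and 5.0e-18 for the G2 list.

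Of the antioxidant list, 19 of 26 rose and 4 fell on both adjustments, led by Slc7a11 (5.22 ± 0.13), Sod2 (4.67 ± 0.10), Hmox1 (3.58 ± 0.08) and the peroxiredoxin gene Prdx5 (3.38 ± 0.09). The antioxidant list gave adjusted p = 1.2e-04 (0.31 estimated). Of the NADPH oxidase list, 7 of 9 rose and 1 fell on both adjustments, with Cybb (2.15 ± 0.08) and Rac2 (2.12 ± 0.07) ahead. The NADPH oxidase list had adjusted p = 0.0016 (0.11 estimated). Of glycolysis genes 15 of 21 rose and 5 fell on both adjustments, with the regulator gene Pfkfb3 (4.36 ± 0.11) and the hexokinase gene Hk3 (1.79 ± 0.06) higher and Pdk1 (-1.67 ± 0.09) lower. The glycolysis list had adjusted p = 0.028 (0.51 estimated) and 0.091 with library-size scaling (0.025 to 0.51 over the camera alternatives). Of 9 measured genes of the mitochondrial genome 8 fell on both adjustments, with mt-Nd4l at -1.17 ± 0.18 and mt-Cytb at -0.83 ± 0.11. The mitochondrial genome list had adjusted p = 0.0069 (0.36 estimated). All 30 type I interferon response genes rose on both adjustments (median 3.85), with Oasl1 (7.86 ± 0.18), Rsad2 (7.50 ± 0.21) and Ifi44 (7.03 ± 0.19) ahead. The interferon response list gave adjusted p = 3.6e-20 (0.051 estimated). Of genes induced by IFNg 22 of 23 rose and 1 fell on both adjustments (adjusted p = 4.5e-14), among them the GTPase gene Gbp4 (8.41 ± 0.24) and Cxcl11 (322-fold higher in counts, 95% interval 57.2 to 12750). Of cholesterol synthesis genes 17 of 23 fell and 1 rose (18 and 1 adjusted over the list alone; adjusted p = 9.8e-05), including Stard4 (-2.88 ± 0.15) and Idi1 (-2.88 ± 0.22). Of 25 ribosomal protein genes 23 fell on both adjustments, with Rpl10a (-2.17 ± 0.08) and Rpl3 (-1.93 ± 0.07) lowest. The ribosomal list had adjusted p = 4.8e-07 (0.36 estimated).

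At 18 h LPS changed 8055 genes, 4055 higher and 4000 lower, of which 1493 and 1764 changed at least 2-fold; with library-size scaling, which moved the median of all genes by -0.42, 2079 were higher and 6984 lower. LPS 18 h replicate 2 stood apart, with a chi-square per gene of 8.65 and 10.7 against the other 2 replicates, which differed by 2.32, and it lay above their mean by a median of 0.39 log2 units for ribosomal protein genes and 0.38 for the antioxidant list; without it and IL-4 18 h replicate 2, 4006 genes were higher and 3932 lower.

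Adding IFNg to LPS, a mixture used to drive strong inflammatory activation, was compared with unstimulated cells at 1 h to find the early response to both signals. The chemokine genes Cxcl9 (10.86 ± 0.23), Cxcl10 (10.55 ± 0.24) and Cxcl11 (2444-fold higher in counts, 95% interval 438 to 96590) rose most. Acod1 (10.24 ± 0.21), Il1a (9.94 ± 0.20) and protease inhibitor genes Serpina3f (at least 249-fold higher) and Serpinb2 (at least 149-fold higher) rose too. Art3 (937-fold higher in counts, 95% interval 320.1 to 4546) rose, but may hold reads from the other strand. Nos2, with no counts in the unstimulated libraries, was at least 33.5-fold higher. The GTPase gene Rhov (-4.31 ± 0.21), Id1 (-3.11 ± 0.23), Smad7, an inhibitor of TGF-beta signals (-3.04 ± 0.21), Angptl4 (-2.82 ± 0.29) and the zinc finger genes Zfp553 (-3.14 ± 0.27) and Zfp157 (-3.03 ± 0.27) fell most. For each of these genes the adjusted p was 6.0e-09 or smaller.

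Nampt rose 6.42-fold, from 99.3 ± 10.7 to 636 ± 40.4 CPM (2.68 ± 0.07, adjusted p = 3.7e-23), and was the only called member of 9 on the NAD+ salvage list, on both adjustments; the list's median was -0.05, its mean 0.24, and its test pointed up (adjusted p = 0.71). In the PARP family 7 of 17 rose and none fell on both adjustments, with Parp14 (2.21 ± 0.13), Parp9 (2.06 ± 0.09) and Tiparp (1.89 ± 0.09) ahead. The PARP list gave adjusted p = 0.011 (0.52 estimated). Of p53 targets 7 of 27 rose and 7 fell (8 and 8 adjusted over the list alone), with Fas (4.50 ± 0.20), Gadd45b (3.39 ± 0.09), Btg2 (2.94 ± 0.10), Cdkn1a (2.43 ± 0.09) and Mdm2 (1.00 ± 0.08) higher; the median was -0.06, the mean 0.43, and the test pointed up (adjusted p = 0.56). Of the antioxidant list 8 of 26 rose and 2 fell on both adjustments, led by Mt2 (5.01 ± 0.13) and Sod2 (3.71 ± 0.10). The antioxidant list had adjusted p = 0.015 (0.88 estimated), and library-size scaling turned it to 6 higher and 11 lower and ended its call (adjusted p = 0.092; 0.017 to 0.88 over the camera alternatives). Of glycolysis genes 5 of 21 rose on both adjustments, with the hexokinase gene Hk2 (2.78 ± 0.11) and the glucose transporter gene Slc2a1 (0.65 ± 0.09) ahead (adjusted p = 0.072), and library-size scaling turned this to 3 higher and 12 lower.

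Of genes induced by IFNg 22 of 23 rose and none fell on both adjustments (median 5.07, adjusted p = 4.2e-31). NF-kappaB feedback genes rose in 18 of 19 cases (adjusted p = 1.0e-29), with Nfkbiz (7.95 ± 0.13) and Cd40 (6.89 ± 0.15) ahead, and cytokine genes in 24 of 26 (adjusted p = 2.5e-32), with Il6, encoding interleukin 6 (at least 85.6-fold higher), Lif (560.2-fold higher in counts, 95% interval 155 to 4633) and the prostaglandin synthase gene Ptgs2 (8.74 ± 0.19); both counts stayed when adjusted over the list alone. Of the type I interferon list 26 of 30 rose (27 adjusted over the list alone), with Ifnb1 (206-fold higher in counts, 95% interval 36.5 to 8180) and Ifit1 (4.69 ± 0.20) ahead. For that list camera gave adjusted p = 2.7e-15 (0.12 estimated). In all 3755 genes were called, 1879 higher and 1876 lower, of which 726 and 549 changed at least 2-fold. Library-size scaling moved the median of all genes by -0.26 and called 6342 genes, 1088 higher and 5254 lower.

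At 18 h the comparison of LPS with IFNg against unstimulated cells asked what the established inflammatory state holds. Nos2 rose from 0.259 ± 0.328 to 5892 ± 266 CPM (14.34 ± 0.20). Cxcl9 (13.74 ± 0.26), Gbp4 (13.59 ± 0.19), Acod1 (12.31 ± 0.22), the paralogs Serpina3g (25490-fold higher in counts, 95% interval 4574 to 1007000) and Serpina3f (6142-fold higher in counts, 95% interval 1102 to 242600), between which reads can be shared, BC023105 (at least 1065-fold higher) and the ion channel gene Clic5 (4637-fold higher in counts, 95% interval 1586 to 22490) also rose most. Slco2b1, an organic anion transporter (at least 282-fold lower), and the division genes Ticrr (at least 104-fold lower), Spc24 (at least 100.5-fold lower), Clspn (1099-fold lower in counts, 95% interval 197 to 43440), Ankle1 (at least 84.7-fold lower) and Ccnb2 (958-fold lower in counts, 95% interval 172 to 37890) fell most. Il1b (8.02 ± 0.34), Tnf (3.78 ± 0.13), Arg1 (5.28 ± 0.33) and the glycolytic enzyme gene Gapdh (1.03 ± 0.07) rose, while Mki67 (-7.02 ± 0.24) and the complex III gene Uqcrc1 (-0.40 ± 0.07) fell. For each of these genes the adjusted p was 1.7e-05 or smaller.

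Nampt rose 15.9-fold, from 99.9 ± 1.23 to 1589 ± 49.7 CPM (3.99 ± 0.08, adjusted p = 4.0e-27), and Nmnat1 rose (0.66 ± 0.17), except that library-size scaling left it at 0.13 (adjusted p = 0.478, the highest over its alternatives, which began at 7.1e-04). Of the salvage list 6 of 9 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.19), and library-size scaling turned this to 1 and 4; the lower gene, Naprt, lost its call without unstimulated 18 h replicate 3 or LPS with IFNg 18 h replicate 1, or with DESeq2. Cd38 rose (7.34 ± 0.27), as did Bst1 (5.05 ± 0.12) and the sirtuin genes Sirt3 (1.63 ± 0.17) and Sirt6 (1.53 ± 0.15); of the hydrolase and sirtuin list 6 of 9 rose and 1 fell on both adjustments (adjusted p = 0.052), against 4 and 3 and a median of -0.08 with library-size scaling. The list was called with that scaling (adjusted p = 0.0497; 0.042 to 0.11 over the camera alternatives) and without unstimulated 18 h replicate 3 and IL-4 18 h replicate 3 (0.042). In the PARP family 14 of 17 rose and 3 fell on both adjustments, with Parp14 (4.16 ± 0.14), Parp10 (4.05 ± 0.11) and Parp11 (3.94 ± 0.09) higher and Parp1 (-2.38 ± 0.09) lower. The PARP list had adjusted p = 2.8e-04 (0.14 estimated). Of the kynurenine pathway, which makes NAD+ from tryptophan, 2 of 7 rose and 2 fell on both adjustments, with Ido1 (179.9-fold higher in counts, 95% interval 31.8 to 7150) and Kynu (6.25 ± 0.28) higher and Haao (10.4-fold lower in counts, 95% interval 3.29 to 53.1) lower; the median was -0.11, the mean 1.22, and the test pointed up (adjusted p = 0.61); the other lower gene, Kyat1, lost its call with DESeq2 or without LPS with IFNg 18 h replicate 3.

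Of the double-strand break repair list 24 of 34 fell and 3 rose on both adjustments, led by Exo1 (281-fold lower in counts, 95% interval 50.1 to 11130) and Fancd2 (-6.09 ± 0.36). The double-strand break list had adjusted p = 2.1e-04 (0.096 estimated). Of base excision and single-strand break repair genes 14 of 24 fell and 5 rose on both adjustments, with Pole (-5.20 ± 0.25) and Ung (-4.41 ± 0.32) among the lower. The base excision list gave adjusted p = 0.0079 (0.12 estimated). Of p53 targets 16 of 27 rose and 5 fell on both adjustments, with Fas (4.30 ± 0.18), Mdm2 (2.95 ± 0.09), Gadd45b (2.89 ± 0.10) and Cdkn1a (2.31 ± 0.09) higher and Sesn1 (-4.14 ± 0.13) lower. The p53 target list gave adjusted p = 0.046 (0.15 estimated), and 0.054 with the replicate block (0.031 to 0.15 over the camera alternatives); library-size scaling gave 10 and 10 and a median of -0.10. S phase genes fell in 24 of 25 cases and G2 and mitosis genes in 24 of 24, on both adjustments, with Rrm2 (-8.63 ± 0.28) and Top2a (-7.63 ± 0.23) as examples. These lists had adjusted p = 8.4e-12 and 7.1e-14, and adjusted p = 0.11 and 0.079 with an estimated correlation. Of the antioxidant list 21 of 26 rose and 3 fell on both adjustments, with Slc7a11 (6.08 ± 0.13), Sod2 (4.10 ± 0.10) and Hmox1 (3.85 ± 0.08) ahead. The antioxidant list gave adjusted p = 3.4e-07 (0.15 estimated). Of the NADPH oxidase list 7 of 9 rose and none fell on both adjustments, with Cybb (2.10 ± 0.08) and Cybc1 (1.62 ± 0.07) ahead. The NADPH oxidase list gave adjusted p = 0.0053 (0.14 estimated).

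Glycolysis genes rose in 17 of 21 cases and fell in 4, on both adjustments, with Pfkfb3 (4.92 ± 0.12), Hk3 (2.71 ± 0.06) and the lactate transporter gene Slc16a3 (2.63 ± 0.09) higher. The glycolysis list gave adjusted p = 1.2e-05 (0.15 estimated). Of TCA cycle genes 6 of 18 rose and 6 fell on both adjustments (adjusted p = 0.57), among them Idh2 (-3.42 ± 0.11) and Suclg2 (-2.61 ± 0.14). Of nuclear complex I genes 12 of 35 fell and 5 rose on both adjustments (adjusted p = 0.21), with Ndufs8 (-1.29 ± 0.15) and Ndufb11 (-1.23 ± 0.11) lowest. Library-size scaling called the TCA cycle list (adjusted p = 0.034; 0.034 to 0.81 over the camera alternatives) and the complex I list (0.018; 0.018 to 0.81). Of the mitochondrial genome 8 of 9 fell on both adjustments, with mt-Nd4l (-1.08 ± 0.18) and mt-Nd3 (-1.05 ± 0.10) lowest. The mitochondrial genome list gave adjusted p = 0.023 (0.39 estimated). All 25 ribosomal protein genes fell on both adjustments, Rpl10a most (-3.51 ± 0.09). The ribosomal list gave adjusted p = 3.5e-11 (0.20 estimated). Of genes induced by IFNg 22 of 23 rose on both adjustments (median 8.09, adjusted p = 8.4e-15). All 10 measured genes of MHC class II presentation rose on both adjustments, with their activator Ciita (5.11 ± 0.14) and H2-Ab1 (3.90 ± 0.12) ahead. The MHC II list had adjusted p = 5.1e-06 (0.11 estimated). All 18 genes of MHC class I and the immunoproteasome rose on both adjustments, with the near-identical H2-Q6 (7.17 ± 0.18) and H2-Q7 (6.80 ± 0.15), which can share reads, and Tap1 (4.43 ± 0.08) ahead. The MHC I list had adjusted p = 1.9e-12 (0.06 estimated).

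The 18 h response to LPS with IFNg held 9215 called genes, 4602 higher and 4613 lower, of which 2106 and 2438 changed at least 2-fold. Library-size scaling moved the median of all genes by -0.54 and gave 2475 higher and 7617 lower.

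**Figure D2:**
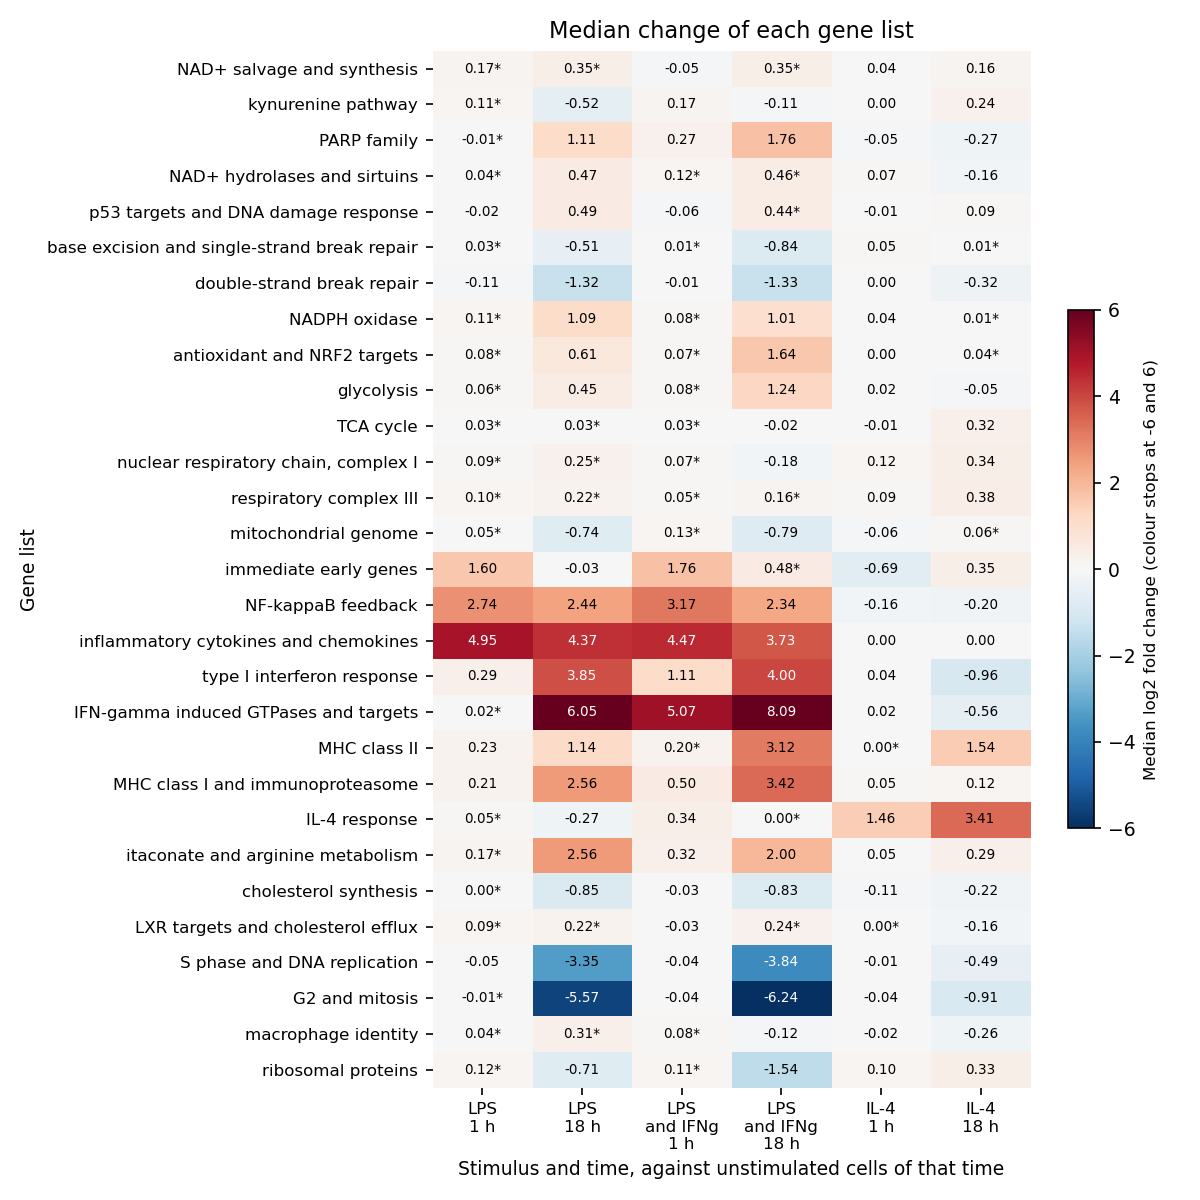
Each cell gives the median log2 fold change of a gene list against unstimulated cells of the same time, with members with a group at 0 placed at their bound, for lists along the vertical axis and stimuli and times along the horizontal axis; colour follows the value and stops at -6 and 6, and an asterisk marks a median whose sign turned with median-of-ratios or library-size scaling. The G2 and mitosis list lies at -5.57 with LPS and -6.24 with LPS and IFNg at 18 h, against -0.91 with IL-4.

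IL-4, the cytokine of alternative activation, was compared with no stimulus at 1 h to give the early response of that program. Arg1 rose 60.3-fold (5.92 ± 0.35), the cholesterol 25-hydroxylase gene Ch25h rose as much (5.91 ± 0.30), and the cytokine signal inhibitors Socs1 (5.42 ± 0.15) and Cish (4.96 ± 0.24) followed, with Cdh1, encoding E-cadherin (4.39 ± 0.33), Ier3 (4.30 ± 0.18), the chemokine gene Ccl7 (4.29 ± 0.14) and the transcription factor gene Nfil3 (4.12 ± 0.14). The phosphatase gene Dusp5 (-2.40 ± 0.16), the growth factor genes Pdgfb (-2.40 ± 0.10) and Vegfa (-1.95 ± 0.19), Smad6 (-2.16 ± 0.26) and Fos (-1.82 ± 0.11) were among those that fell most. Of the IL-4 response list 21 of 28 rose and none fell on both adjustments (median 1.46, adjusted p = 1.7e-31), among them Pdcd1lg2 (23.8-fold higher in counts, 95% interval 6.25 to 202). Immediate early genes fell in 12 of 22 cases and rose in 5 (12 and 7 adjusted over the list alone), with Fosb lower (-1.26 ± 0.18) and Egr2 higher (2.30 ± 0.11). The immediate early list had adjusted p = 0.027 (0.93 estimated). Of NF-kappaB feedback genes 5 of 19 fell and 4 rose (7 and 5 adjusted over the list alone; adjusted p = 0.21), with Nfkbiz (-1.79 ± 0.25) and Bcl3 (-1.45 ± 0.20) lowest.

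Tnf fell from 34.6 ± 7.59 to 11.2 ± 2.58 CPM (-1.63 ± 0.15, adjusted p = 1.8e-09). Of p53 targets 5 of 27 fell and 3 rose (5 and 5 adjusted over the list alone; adjusted p = 0.75), with Mdm2 (2.01-fold lower) and Gadd45b (-0.83 ± 0.11) lower and the kinase gene Plk3 (1.29 ± 0.10) and Cdkn1a (0.46 ± 0.08) higher. Nampt was 0.25 ± 0.07 (adjusted p = 0.028), and leaving out unstimulated 1 h replicate 1 or 2 or IL-4 1 h replicate 1 or 3 ended that call (adjusted p from 0.0999 to 0.217, against 0.0031 at the lowest of all alternatives). Hmox1 was -0.31 ± 0.07 (adjusted p = 0.0052) and lost its call without IL-4 1 h replicate 1 (adjusted p = 0.0749, the highest over its alternatives, which began at 0.0010). IL-4 changed 829 genes at 1 h, 411 higher and 418 lower, of which 141 and 81 changed at least 2-fold.

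At 18 h the comparison of IL-4 with no stimulus asked what the alternatively activated state holds. Retnla, encoding the secreted protein FIZZ1, had no counts in unstimulated cells and 204 ± 60.7 CPM after IL-4 (at least 1303-fold higher). Arg1 rose 1251-fold (10.29 ± 0.21), and the lectin gene Mgl2 (8.65 ± 0.21), the ribonuclease gene Rnase2a (at least 296-fold higher), Msx3 (at least 80.5-fold higher), the receptor gene Il31ra (248-fold higher in counts, 95% interval 44.2 to 9838), Pdcd1lg2 (123-fold higher in counts, 95% interval 33.8 to 1023) and the sodium channel gene Scn3a (92-fold higher in counts, 95% interval 31.2 to 448) also rose most. The chemokine receptor gene Cx3cr1 (-6.51 ± 0.27), the costimulatory ligand gene Icosl (-3.50 ± 0.26), Fcrl1 (-3.39 ± 0.26), the kinase gene Dmpk (-3.37 ± 0.21), Notch4 (-3.19 ± 0.28) and the LPS co-receptor gene Cd14 (-2.96 ± 0.11) fell most. For each of these genes the adjusted p was 9.1e-09 or smaller.

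Of the IL-4 response list 26 of 28 rose and 1 fell on both adjustments (median 3.41, adjusted p = 1.2e-28). Of MHC class II genes 8 of 10 rose and none fell on both adjustments, with Ciita (2.47 ± 0.16) and H2-Ab1 (1.80 ± 0.12) ahead. The MHC II list gave adjusted p = 2.5e-08 (0.15 estimated). Of type I interferon response genes 25 of 30 fell and none rose on both adjustments, with Ifit3 (-2.65 ± 0.32) and Oas2 (-2.02 ± 0.23) lowest. The interferon response list gave adjusted p = 1.3e-09 (0.40 estimated). Of the macrophage identity list 11 of 20 fell and 2 rose on both adjustments, with the Fc receptor gene Fcgr1 (-1.96 ± 0.09) and Mpeg1 (-1.71 ± 0.09) among the lower. The identity list had adjusted p = 8.8e-05 (0.40 estimated). Of S phase genes 22 of 25 fell (23 adjusted over the list alone), and of G2 and mitosis genes 24 of 24 fell on both adjustments, with Tk1 (-0.97 ± 0.13), Cenpf (-1.38 ± 0.15) and Mki67 (-1.18 ± 0.14) as examples. These lists had adjusted p = 5.1e-05 and 5.5e-08, and adjusted p = 0.41 and 0.39 with an estimated correlation.

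Of TCA cycle genes 16 of 18 rose and 1 fell (17 and 1 adjusted over the list alone), with Mdh2 (0.70 ± 0.08) and Suclg1 (0.63 ± 0.10) higher and Suclg2 (-0.60 ± 0.11) lower. The TCA cycle list had adjusted p = 3.2e-06 (0.15 estimated). Of nuclear complex I genes 23 of 35 rose and none fell (28 adjusted over the list alone), Ndufa6 most (0.73 ± 0.11). The complex I list had adjusted p = 1.6e-06 (0.41 estimated). Of complex III genes 9 of 13 rose and none fell on both adjustments, with Cyc1 (0.75 ± 0.08) and Uqcrc1 (0.69 ± 0.07) ahead. The complex III list had adjusted p = 0.0012 (0.40 estimated). IL-4 18 h replicate 2 lay apart from replicates 1 and 3 of its group, with a chi-square per gene of 6.97 and 4.32 against 3.10 between those; without it and LPS 18 h replicate 2, 2217 genes were higher and 2303 lower, and 16 complex I genes rose with a median of 0.22 in place of 0.34. In the PARP family 8 of 17 fell (4 without unstimulated 18 h replicate 3 and IL-4 18 h replicate 3) and 2 rose on both adjustments (adjusted p = 0.077), with Parp8 (-1.10 ± 0.14) and Parp14 (-0.92 ± 0.13) lowest and Tiparp higher (0.54 ± 0.10). Parp1 fell (-0.34 ± 0.08) and Nampt rose (0.27 ± 0.07), both by less than 2-fold. Cybb fell (-1.04 ± 0.08), while Hmox1 (0.47 ± 0.07), Cdkn1a (0.67 ± 0.08) and Gadd45b (0.45 ± 0.11) rose, and Mdm2 was not called (-0.03 ± 0.09). Sod2 was 0.30 ± 0.10 (adjusted p = 0.021) and lost its call without unstimulated 18 h replicate 1 or IL-4 18 h replicate 2 or 3 (adjusted p from 0.0576 to 0.183, against 0.0024 at the lowest of all alternatives). IL-4 changed 4999 genes at 18 h, 2431 higher and 2568 lower, of which 429 and 556 changed at least 2-fold; library-size scaling gave 1957 higher and 3077 lower.

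**Figure D3:**
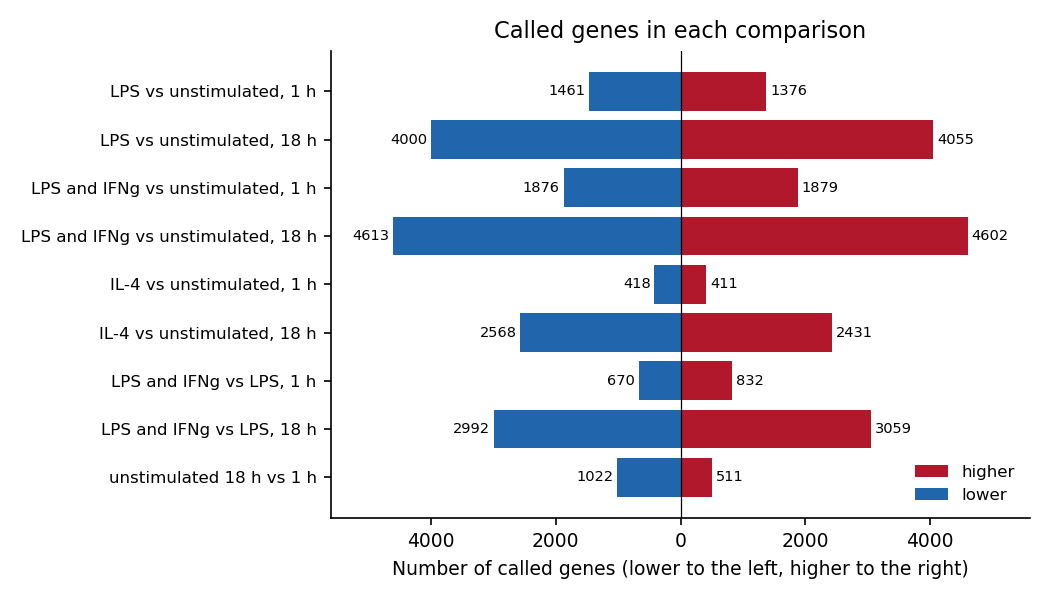
Bars give the number of genes called higher (right) and lower (left) in each comparison of groups on a linear axis from 0, with the numbers at their ends. LPS with IFNg at 18 h changed 4602 genes up and 4613 down, and IL-4 at 1 h changed 411 and 418.

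LPS with IFNg was compared with LPS alone at 1 h to find what IFNg adds, though their LPS doses may differ. Cxcl9 was 5715-fold higher in counts, 95% interval 1955 to 27720, and the GTPase genes Iigp1 (6.91 ± 0.27), Tgtp1 (6.46 ± 0.23) and its near-identical paralog Tgtp2 (6.07 ± 0.23), Cxcl11 (7.67 ± 0.22), Serpina3f (515-fold higher in counts, 95% interval 92.1 to 20370), Serpina3g (76.5-fold higher in counts, 95% interval 20.9 to 636) and the kinase gene Lck (63.2-fold higher in counts, 95% interval 21.4 to 309) rose most. Slco4a1 (-3.90 ± 0.26), the cytokine genes Il23a (-3.87 ± 0.35), Il10 (-3.36 ± 0.13) and Csf2 (-2.80 ± 0.22), and Sema6d (-2.53 ± 0.26) were lower than with LPS alone. Nos2 was at least 23.1-fold higher, and Il1b was lower (-1.46 ± 0.16). Nampt was 5.04-fold higher (2.33 ± 0.07, adjusted p = 6.4e-21). The NAD+ salvage list had 1 higher and 1 lower of 9 on both adjustments, a median of -0.14, a mean of 0.13 and a test that pointed down (adjusted p = 0.98); the lower gene, Slc25a51 (-0.33 ± 0.09), lost its call without replicate 1 or 3 of either group (adjusted p from 0.0021 to 0.0859 over its alternatives). In the PARP family 5 of 17 were higher and none lower (6 adjusted over the list alone), with Parp9 (1.78 ± 0.09) and Parp14 (1.53 ± 0.12) ahead. The PARP list gave adjusted p = 1.6e-04 (0.35 estimated). Of genes induced by IFNg 21 of 23 were higher and 1 lower on both adjustments (median 4.53, adjusted p = 1.4e-50). Of type I interferon genes 22 of 30 were higher and 1 lower (23 and 1 adjusted over the list alone), with Mx2 (2.62 ± 0.18) and Ifit2 (2.60 ± 0.15) ahead. That list had adjusted p = 3.3e-14 (0.35 estimated). Cytokine genes went both ways, 9 higher and 10 lower of 26 (10 and 13 adjusted over the list alone; adjusted p = 0.82), with Il12b higher (3.15 ± 0.21). In all 1502 genes were called, 832 higher and 670 lower, of which 343 and 155 differed at least 2-fold, and library-size scaling gave 687 higher and 1011 lower.

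The same comparison at 18 h had the same limit. Serpina3g (7.40 ± 0.15), Serpina3f (6.84 ± 0.14), the actin-binding gene Cnn3 (7.11 ± 0.15), Bcl2l14 (at least 80.7-fold higher), Mb21d2 (158-fold higher in counts, 95% interval 28 to 6280), Pacsin1 (93.7-fold higher in counts, 95% interval 31.8 to 457), Clic5 (6.34 ± 0.14) and the amino acid transporter gene Slc6a19 (6.29 ± 0.17) were higher by the most. Haptoglobin gene Hp (-6.87 ± 0.25), Serpinb2 (-5.13 ± 0.27), U90926 (-5.03 ± 0.21), the chemokine receptor gene Ccr3 (-4.98 ± 0.33), Cxcl3 (-4.55 ± 0.21) and Saa1 (-4.49 ± 0.35) were lower by the most. Nampt (2.14 ± 0.07), Mdm2 (1.14 ± 0.08), Gadd45b (1.22 ± 0.09), Tnf (1.04 ± 0.11) and Nos2 (3.97 ± 0.10) were higher than with LPS alone, and Cd38 (-1.20 ± 0.12), Parp1 (-0.91 ± 0.10), Sod2 (-0.57 ± 0.09), Il1b (-1.96 ± 0.17), Arg1 (-3.17 ± 0.13) and Mki67 (-1.81 ± 0.37) were lower. For each of these genes the adjusted p was 1.6e-04 or smaller.

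Of glycolysis genes 17 of 21 were higher and 1 lower on both adjustments, with the phosphofructokinase gene Pfkp (2.84 ± 0.08) and Slc16a3 (1.53 ± 0.09) ahead. The glycolysis list had adjusted p = 2.4e-09 (0.17 estimated). Nuclear complex I genes were lower in 20 of 35 cases and higher in none (21 adjusted over the list alone), Ndufs8 most (-1.08 ± 0.15); without LPS 18 h replicate 2 and IL-4 18 h replicate 2, 17 were lower and the median was -0.21 in place of -0.34. The complex I list gave adjusted p = 1.3e-04 (0.65 estimated). Of the antioxidant list 18 of 26 were higher and 6 lower (18 and 7 adjusted over the list alone), with Mt2 (3.02 ± 0.14) and the quinone reductase gene Nqo1 (2.37 ± 0.21) ahead; without these 2 libraries 19 were higher and 3 lower. The antioxidant list had adjusted p = 1.3e-04 (0.43 estimated). TCA cycle genes went both ways, 5 higher and 6 lower of 18 on both adjustments (adjusted p = 0.70), Idh2 the lowest (-2.06 ± 0.13). Of p53 targets 11 of 27 were higher and 11 lower (11 and 13 adjusted over the list alone; adjusted p = 0.90), and library-size scaling turned the median to -0.03; Pmaip1 (1.78 ± 0.12) and Fas (1.75 ± 0.14) were higher and Sesn1 (-1.93 ± 0.15) lower. Of the kynurenine pathway 3 of 7 were higher and none lower on both adjustments (adjusted p = 0.098, and 0.041 with library-size scaling; 0.041 to 0.41 over the camera alternatives), with Ido1 (74.4-fold higher in counts, 95% interval 20.3 to 619.8) and Kynu (5.99 ± 0.29) ahead. Of genes induced by IFNg 22 of 23 were higher (23 adjusted over the list alone; adjusted p = 2.7e-17), with Gbp4 (5.18 ± 0.10) and Cxcl9 (4.76 ± 0.14) among them. Of MHC class II genes 8 of 10 were higher and 1 lower (9 and 1 adjusted over the list alone), Ciita most (5.50 ± 0.15). The MHC II list had adjusted p = 4.3e-06 (0.22 estimated). Of the macrophage identity list 14 of 20 were lower and 3 higher (15 and 3 adjusted over the list alone), with Cx3cr1 (-3.06 ± 0.51) lower and Mertk higher (1.91 ± 0.10). The identity list gave adjusted p = 8.6e-05 (0.41 estimated). Of 8 measured neutrophil and granulocyte precursor markers 5 were lower and none higher on both adjustments, with Mmp8 (-2.62 ± 0.20) and Ltf (-2.55 ± 0.23) lowest. The neutrophil list had adjusted p = 0.0015 (0.13 estimated).

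In all 6051 genes were called, 3059 higher and 2992 lower, of which 847 and 817 differed at least 2-fold. Library-size scaling gave 2329 higher and 3912 lower, and leaving out LPS 18 h replicate 2 and IL-4 18 h replicate 2 gave 2937 and 2805.

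**Figure D4:**
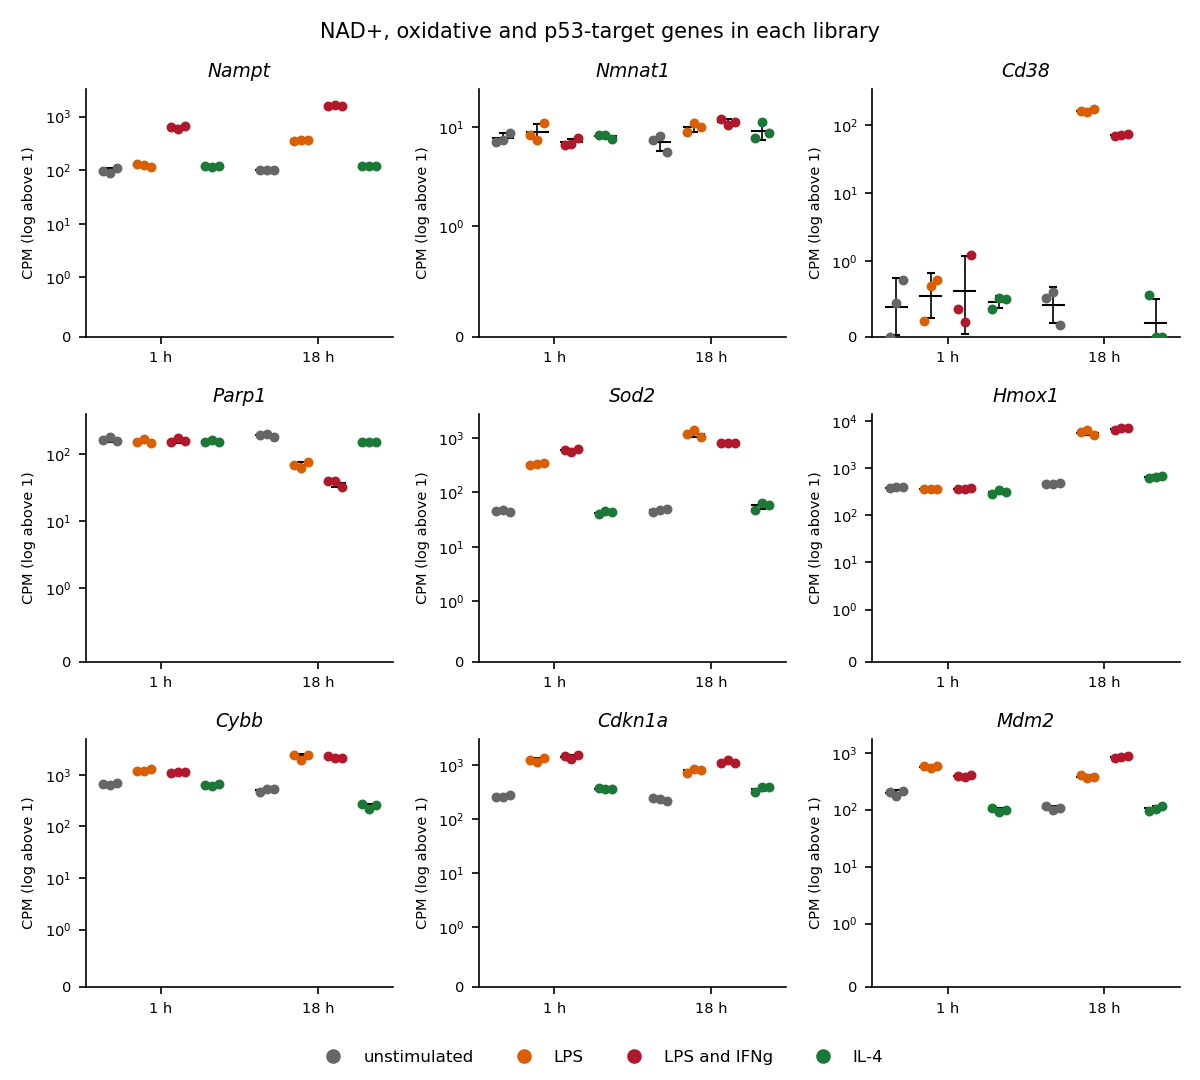
Points are libraries, bars the mean ± SD of 3 libraries, with the lower end of the SD stopped at 0, and the vertical axis is CPM, logarithmic above 1 and linear below. Nampt lies highest in the 18 h libraries of LPS with IFNg, and Cd38 passes 1 CPM by far in the 18 h LPS groups alone.

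**Figure D5:**
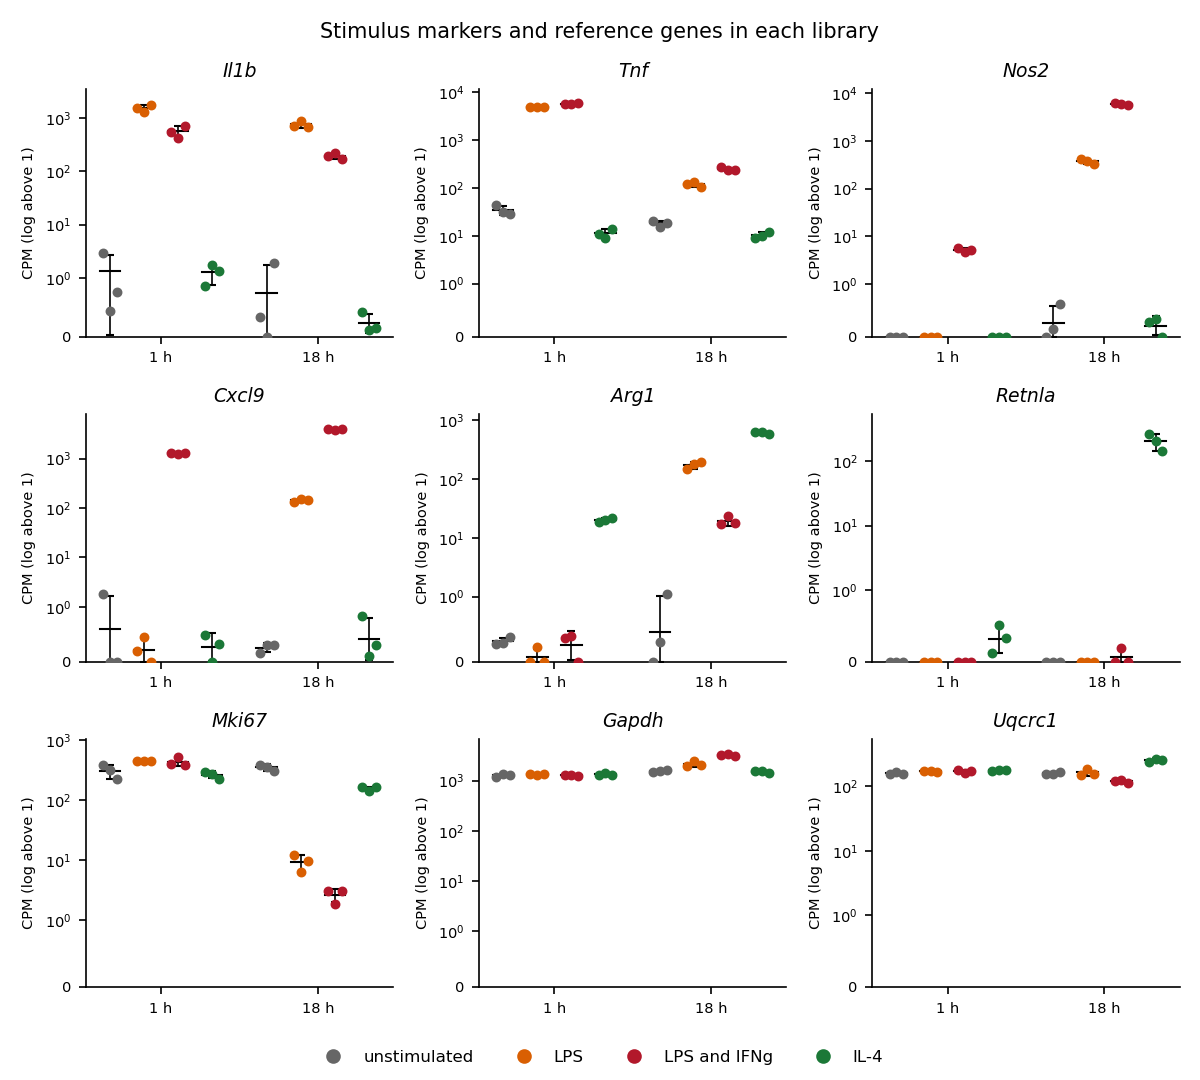
Points are libraries, bars the mean ± SD of 3 libraries, with the lower end of the SD stopped at 0, and the vertical axis is CPM, logarithmic above 1 and linear below. Nos2 and Cxcl9 lie higher with LPS and IFNg than with LPS alone, and Retnla passes 1 CPM only in the 18 h IL-4 libraries.

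Unstimulated cells at 18 h and 1 h were compared to show what time in culture alone changed. The kinase gene Dmpk (1.53 ± 0.17), Cx3cr1 (1.21 ± 0.16), Notch4 (1.12 ± 0.22), Ankrd37 (1.11 ± 0.23), the integrin gene Itgal (0.99 ± 0.15), Olfml3 (0.99 ± 0.18) and Raet1d (0.97 ± 0.21) rose most. Etv1 was 0.96 ± 0.23 and lost its call without unstimulated 1 h replicate 1 (0.71, adjusted p = 0.0616, the highest over its alternatives, which began at 1.3e-04). The immediate early genes Egr3 (-3.32 ± 0.23) and Fosb (-2.71 ± 0.22), Thbs1, encoding thrombospondin 1 (-2.25 ± 0.31), the adenosine receptor gene Adora2b (-2.25 ± 0.24), Ms4a4a (4-fold lower) and the histone demethylase gene Kdm6b (-1.95 ± 0.19) fell most. Of immediate early genes 14 of 22 fell and none rose (15 adjusted over the list alone). The immediate early list gave adjusted p = 3.3e-12 (0.066 estimated). NF-kappaB feedback genes fell in 8 of 19 cases (9 adjusted over the list alone), with Nfkbia (-0.86 ± 0.09) lowest. The NF-kappaB list had adjusted p = 1.0e-06 (0.20 estimated). Of MHC class II genes 7 of 10 fell (8 adjusted over the list alone), Ciita most (-0.98 ± 0.19). The MHC II list gave adjusted p = 1.1e-05 (0.20 estimated). Of LXR target genes 4 of 11 fell (7 adjusted over the list alone), Abca1 most (-0.91 ± 0.17); Pltp and Apoe lost their calls without unstimulated 1 h replicate 3. The LXR list had adjusted p = 0.0028 (0.20 estimated). S phase genes rose in 20 of 25 cases (21 adjusted over the list alone, with 1 lower), with Cdc6 (0.73 ± 0.15) and Chaf1a (0.67 ± 0.13) ahead. The S phase list had adjusted p = 4.2e-10 (0.20 estimated). Of glycolysis genes 13 of 21 rose and 2 fell on both adjustments, with Pfkl (0.60 ± 0.11) higher and Pfkfb3 (-0.72 ± 0.12) lower. The glycolysis list gave adjusted p = 7.2e-05 (0.27 estimated).

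Mdm2 (-0.87 ± 0.09), Gadd45b (-0.91 ± 0.11), Tnf (-0.95 ± 0.14) and Cybb (-0.38 ± 0.08) fell between 1 h and 18 h, Hmox1 rose (0.29 ± 0.07), and Nampt was not called (0.01 ± 0.07). Gapdh was 0.30 ± 0.07 (adjusted p = 0.0058) and lost its call without unstimulated 1 h replicate 1 (adjusted p = 0.0544, the highest over its alternatives, which began at 2.4e-04). In all 1533 genes were called, 511 higher and 1022 lower, of which 19 and 84 changed at least 2-fold, and library-size scaling turned this to 998 higher and 681 lower. The count fell to 867 without unstimulated 18 h replicate 1.

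The LPS response at 18 h was tested against that at 1 h, to tell early from late response genes. The type I interferon list was stronger at 18 h in 29 of 30 members and weaker in none, on both adjustments, with the antiviral genes Mx1 (7.06 ± 0.27) and Irf7 (6.28 ± 0.27) ahead. The list gave adjusted p = 2.4e-18 (0.084 estimated). Immediate early genes were lower at 18 h in 17 of 22 cases and higher in 2, on both adjustments. Egr2 (-7.94 ± 0.24) and Egr1 (-5.49 ± 0.36) fell by more than any 1 h rise of the list, to below unstimulated cells. The list had adjusted p = 1.5e-06 (0.084 estimated). In the PARP family 10 of 17 were higher and 1 lower (10 and 2 adjusted over the list alone), Parp11 (3.51 ± 0.16) and Parp10 (3.04 ± 0.16) most. The PARP list had adjusted p = 0.0012 (0.24 estimated). Of the mitochondrial genome 8 of 9 were lower on both adjustments, such as mt-Nd2 (-0.81 ± 0.12). The list had adjusted p = 0.012 (0.41 estimated). The responses of Nampt (1.51 ± 0.10), Cd38 (8.03 ± 1.24), Hmox1 (3.70 ± 0.11), Sod2 (1.77 ± 0.14) and Cybb (1.29 ± 0.11) were higher at 18 h, and those of Tnf (-4.41 ± 0.18), Gadd45b (-1.65 ± 0.14), Parp1 (-1.37 ± 0.12) and Mki67 (-5.77 ± 0.24) were lower. Mdm2 was 0.29 ± 0.12 (adjusted p = 0.036), and lost its call without LPS 1 h replicate 2, LPS 18 h replicate 1, unstimulated 1 h replicate 1 or 3, or unstimulated 18 h replicate 2 or 3 (adjusted p from 0.0523 to 0.115). With median-of-ratios scaling it was 0.27 and with library-size scaling 0.06, and its adjusted p over all alternatives ran from 0.0072 to 0.692. In all 6919 genes differed, 3452 higher and 3467 lower, against 2378 and 4616 with library-size scaling.

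The same test for LPS with IFNg asked how the combined response changes with time. The type I interferon list was higher at 18 h in 29 of 30 members on both adjustments, Mx1 most (7.21 ± 0.25). The list had adjusted p = 1.8e-12 (0.16 estimated). All 10 measured MHC class II genes were higher on both adjustments, Ciita most (4.63 ± 0.23). The MHC II list had adjusted p = 4.9e-06 (0.16 estimated). Of glycolysis genes 16 of 21 were higher and 5 lower on both adjustments, with Pfkfb3 (5.04 ± 0.16) and Slc16a3 (2.71 ± 0.13) ahead. The glycolysis list had adjusted p = 1.6e-04 (0.23 estimated). Immediate early genes were lower in 16 of 22 cases and higher in 2 (16 and 3 adjusted over the list alone), with Egr2 (-7.63 ± 0.22) and Myc (-7.12 ± 0.26) lowest. The immediate early list gave adjusted p = 2.1e-04 (0.18 estimated). The responses of Nampt (1.31 ± 0.10), Cd38 (6.58 ± 1.16), Mdm2 (1.96 ± 0.12) and Hmox1 (3.93 ± 0.11) were higher at 18 h and those of Parp1 (-2.32 ± 0.12), Tnf (-3.59 ± 0.18) and Uqcrc1 (-0.49 ± 0.10) were lower. In all 8171 genes differed, 4063 higher and 4108 lower, against 2902 and 5321 with library-size scaling.

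For IL-4 the response at 18 h was tested against that at 1 h in the same way. Of the IL-4 response list 15 of 28 were higher at 18 h and 2 lower (18 and 2 adjusted over the list alone; adjusted p = 4.2e-15), with Mgl2 (5.56 ± 0.64) and the chemokine gene Ccl22 (4.08 ± 0.40) ahead. MHC class II genes were higher in 8 of 10 cases on both adjustments, Ciita most (2.07 ± 0.23). The MHC II list gave adjusted p = 4.4e-09 (0.15 estimated). Type I interferon genes were lower in 20 of 30 cases (26 adjusted over the list alone), with Ifit3 (-2.45 ± 0.42) and Irf7 (-2.31 ± 0.29) among them. The interferon response list gave adjusted p = 6.5e-11 (0.26 estimated). Of TCA cycle genes 13 of 18 were higher and 1 lower (14 and 1 adjusted over the list alone), with Mdh2 (0.75 ± 0.12) and Sdhb (0.68 ± 0.11) ahead. The TCA cycle list gave adjusted p = 8.3e-06 (0.15 estimated). In all 2746 genes differed, 1293 higher and 1453 lower, against 984 and 1770 with library-size scaling.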

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

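The pair of fits without 2 libraries at once, the 100 splits of the interactions, the comparison of untested reads with its tests, and the demand that the interval of the receptor ratio lie under its bound were chosen only after results were seen; the other tests reported here were not. Responses that differed between the time points are given as values with no explanation. The LPS response differed for 6919 genes. When time labels were exchanged within the LPS and within the unstimulated libraries, 1 of 100 splits gave as many, the real one. The highest other gave 6755. The 13 splits that exchanged unstimulated libraries alone gave 6351 to 6755, so the count followed the division of the LPS libraries by time. That division has too few alternatives to exclude chance, and chance in the difference from unstimulated cells was not tested. The lists counted 29 type I interferon genes and 10 PARP genes higher, and 17 immediate early and 8 mitochondrial genome genes lower. Log2 differences were 7.06 ± 0.27 for Mx1, 6.65 ± 0.74 for Ifi44, 6.28 ± 0.27 for Irf7 and 6.23 ± 0.52 for Isg20, and 3.51 ± 0.16 for Parp11, 3.04 ± 0.16 for Parp10, 2.71 ± 0.11 for Parp12 and 2.44 ± 0.18 for Parp14. Immediate early genes had -7.94 ± 0.24 for Egr2 and -5.49 ± 0.36 for Egr1, and adjusted p = 3.6e-07 for Egr3 and 1.6e-08 for Fosb, which had too few counts in a group for a fold. Mitochondrial transcripts had -1.02 ± 0.25 for mt-Nd4l, -0.90 ± 0.18 for mt-Nd4, -0.87 ± 0.15 for mt-Cytb and -0.81 ± 0.12 for mt-Nd2. Among the fixed genes the differences were 1.51 ± 0.10 for Nampt, -1.37 ± 0.12 for Parp1, 8.03 ± 1.24 for Cd38, -0.44 ± 0.12 for Cdkn1a, -1.65 ± 0.14 for Gadd45b, 1.77 ± 0.14 for Sod2, 1.29 ± 0.11 for Cybb, 3.70 ± 0.11 for Hmox1, -4.41 ± 0.18 for Tnf and -5.77 ± 0.24 for Mki67. Gapdh had 0.39 ± 0.10, and with library-size scaling 0.16 (adjusted p = 0.157; 4.7e-04 to 0.157 over the alternatives). Mdm2 had 0.29 ± 0.12, and its call ended without unstimulated 1 h replicate 3 (0.23) and without any 1 of 5 other libraries, with 0.0072 to 0.692 as the range of adjusted p over the alternatives. Arg1 gave adjusted p = 2.5e-06 and Cxcl9 3.9e-08; without unstimulated 1 h replicate 1 Cxcl9 gave 0.945, with 3.3e-26 to 0.945 over the alternatives.

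The response to LPS with IFNg differed for 8171 genes. Of 100 splits 1 gave as many, the real one, with 8007 in the highest other. The 12 that exchanged unstimulated libraries alone gave 7643 to 8007, so here too chance in the division by time was not excluded. Chance in the difference was not tested. Higher at 18 h were 29 type I interferon, 10 MHC class II and 16 glycolysis genes, and lower were 16 immediate early genes. The differences were 7.21 ± 0.25 for Mx1, 6.42 ± 0.71 for Ifi44, 5.39 ± 0.51 for Isg20 and 5.36 ± 0.26 for Irf7, 4.63 ± 0.23 for Ciita, 3.81 ± 0.19 for H2-DMa, 3.65 ± 0.17 for H2-Ab1 and 3.46 ± 0.18 for H2-Eb1, and 5.04 ± 0.16 for Pfkfb3, 2.71 ± 0.13 for Slc16a3, 2.42 ± 0.08 for Hk3 and 1.89 ± 0.10 for Pfkp. Egr2 had -7.63 ± 0.22, Myc -7.12 ± 0.26, Egr1 -6.48 ± 0.32 and Fosb -4.17 ± 0.60. For the fixed genes they were 1.31 ± 0.10 for Nampt, -2.32 ± 0.12 for Parp1, 6.58 ± 1.16 for Cd38, 1.96 ± 0.12 for Mdm2, -0.51 ± 0.14 for Gadd45b, 1.36 ± 0.11 for Cybb, 3.93 ± 0.11 for Hmox1, 1.03 ± 0.10 for Gapdh, -0.49 ± 0.10 for Uqcrc1, -3.59 ± 0.18 for Tnf, 5.57 ± 1.26 for Arg1 and -7.53 ± 0.28 for Mki67. Nmnat1 had 0.79 ± 0.25 and Sod2 0.39 ± 0.14, and with library-size scaling these were 0.52 (adjusted p = 0.0628; 0.0040 to 0.0628 over the alternatives) and 0.12 (adjusted p = 0.416; 9.0e-04 to 0.416). Cxcl9 had 2.88 ± 0.91, but -2.14 (adjusted p = 0.224; 1.6e-04 to 0.27 over the alternatives) without unstimulated 1 h replicate 1.

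The IL-4 response differed for 2746 genes, and 6 of 100 splits gave as many, so chance was not excluded. The highest other split, with 4702, exchanged all 3 unstimulated libraries between the times, so that their change with time was added to that of the IL-4 libraries instead of subtracted. Another 4 splits exchanged 2 unstimulated libraries (3932, 3203 and 2937) or 1 (2773) and left the IL-4 libraries at their times, which points to a structure of the samples by time. Higher at 18 h were 15 IL-4 response, 8 MHC class II and 13 TCA cycle genes (7 without unstimulated 18 h replicate 3 and IL-4 18 h replicate 3), and lower were 20 type I interferon genes. They had 5.56 ± 0.64 for Mgl2, 4.37 ± 1.09 for Arg1, 4.08 ± 0.40 for Ccl22 and 4.07 ± 0.40 for Ear2, 2.07 ± 0.23 for Ciita, 1.88 ± 0.19 for H2-DMa, 1.86 ± 0.18 for H2-Eb1 and 1.81 ± 0.17 for H2-Ab1, 0.75 ± 0.12 for Mdh2, 0.68 ± 0.11 for Sdhb and 0.52 ± 0.14 for Suclg1, and -2.45 ± 0.42 for Ifit3, -2.31 ± 0.29 for Irf7 and -2.08 ± 0.44 for Ifit1. Suclg2 of the TCA cycle list was lower, at -0.76 ± 0.15. Ifi44 had -2.48 ± 0.75, which lost its call without unstimulated 18 h replicate 2 (-2.19, adjusted p = 0.0582; 7.1e-04 to 0.0715 over the alternatives) and without IL-4 18 h replicate 2 (-1.91, adjusted p = 0.0715). The fixed genes had 0.97 ± 0.12 for Mdm2, 1.29 ± 0.16 for Gadd45b, -0.95 ± 0.11 for Cybb, 0.78 ± 0.10 for Hmox1, 0.55 ± 0.10 for Uqcrc1, 0.81 ± 0.23 for Tnf and -0.97 ± 0.20 for Mki67. Without unstimulated 18 h replicate 3 and IL-4 18 h replicate 3, Tnf gave 0.71 (adjusted p = 0.0562; 3.6e-05 to 0.0562 over the alternatives) and Suclg1 0.47 (adjusted p = 0.0532; 0.0026 to 0.0532).

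In each of the 9 comparisons of 2 groups, 1 of 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real counts were 2837 and 8055 for LPS at 1 h and 18 h, 3755 and 9215 for LPS with IFNg, 829 and 4999 for IL-4, 1502 and 6051 for LPS with IFNg against LPS, and 1533 for unstimulated cells, and the highest other was 0 in each.

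Reads outside the tested genes set 2 libraries apart: 6418 untested genes had a read in unstimulated 18 h replicate 3 and 5137 in IL-4 18 h replicate 3, against 2874 to 4102 in the other 22. Deeper sequencing was excluded, since after thinning all libraries to the smallest total 18137 and 16945 genes had a read, against 14925 to 16000. RNA from cells of another type would fall in abundant transcripts, but the 100 most read untested genes held 7.68% and 9.44% of untested reads, below the 10.5% to 14.6% of the other libraries. Genomic DNA may be the source but was not settled: per Mb of exon, the excess of reads in 1314 olfactory and vomeronasal receptor genes was 0.223 (95% interval 0.176 to 0.276) and 0.208 (0.150 to 0.278) of that in other untested genes. Both ratios lay under the bound of 0.25 set against it and both intervals, of counting error only, reached above it. No other explanation was tested.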

How the results depend on the processing

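The fits without 2 libraries were chosen after seeing the data, and all other alternatives before. A count of calls was kept if within 1.5 times of the reported one, whatever their direction. All 12 counts kept to this under DESeq2, limma-voom, median-of-ratios scaling, no filter on low counts, fits on the compared groups alone and the replicate block, and 10 of 12 under library-size scaling and at a threshold of 0.01. Library-size scaling, which drops the composition factors, called 4443 (LPS) and 6342 (LPS with IFNg) genes at 1 h. At 18 h it reversed 139 and 426 calls, in that order. At 0.01 unstimulated cells gave 785 and the IL-4 interaction 1655, fewer by construction. Leaving out 1 replicate kept 86 of 90 counts. The other 4 were in unstimulated cells at 18 h against 1 h, which ran from 867 (without 18 h replicate 1) to 1545, with 874 and 999 without 1 h replicates 3 and 1 and 990 without 18 h replicate 2; the cause was not tested, beyond the fewer samples. The lowest and highest counts in the other comparisons were 2323 and 2602 (LPS, 1 h), 7605 and 7826 (LPS, 18 h), 3195 and 3459 (LPS with IFNg, 1 h), 8760 and 8851 (18 h), 646 and 734 (IL-4, 1 h), 4046 and 4947 (18 h), 1278 and 1332 (LPS with IFNg against LPS, 1 h), 5383 and 5761 (18 h), and 6571 and 6904, 7833 and 7958, and 2235 and 2740 for the LPS, LPS with IFNg and IL-4 interactions. Without the library pairs, 5 of 5 and 7 of 7 counts were kept.

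With the replicate block the counts in the same order were 3046, 8268, 4057, 9355, 959, 5422, 1645 and 6308, 2013 for unstimulated cells, and 7145, 8324 and 3090 for the interactions. Of 84 same-number pairs between groups, 34 had correlated deviations above 0.1 (median 0.072, against -0.033 for different numbers). Of 24 libraries 21 had their highest mean correlation with their own number, so replicates may share an effect.

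Of 685 named gene results, the direction and the side of the threshold stayed in 678 with DESeq2, 680 with limma-voom, 684 with median-of-ratios scaling, 680 with no filter, 684 with the replicate block and 657 with library-size scaling, and in 4674 of 4734 fits without 1 replicate. Library-size scaling turned 4 directions: Uqcrc1 became -0.38 in LPS at 18 h (adjusted p = 1.4e-05; 1.4e-05 to 0.973 over the alternatives), and in LPS with IFNg Gapdh became -0.26 at 1 h (adjusted p = 0.0019; 0.0019 to 1), Uqcrc1 -0.18 at 1 h (adjusted p = 0.031; 0.031 to 0.751) and Nadk2 -0.00808 at 18 h (adjusted p = 0.967; 0.0018 to 0.967). Cxcl9 in the LPS with IFNg interaction ran from -2.14 to 3.49 without 1 replicate; the cause was not tested.

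Of 105 list results, 65 lost their call with an estimated correlation, so those calls rest on the preset 0.01. The other 40 include lists that had no call. The test fry, which does not compare a list with other genes, left 87 lists called or uncalled as camera did, called 16 more and 1 fewer, and gave NAD+ salvage in LPS with IFNg against LPS at 1 h the other direction (adjusted p = 7.8e-05); the 2 ask different questions. The replicate block kept 104, library-size scaling 97, and the fits without the library pairs 48 of 48 and 67 of 68. Depth limited the tests to 12765 genes, and in simulated counts a 1.5-fold change was called in 51 of 67 genes for LPS at 1 h but in 22 of 67 for its interaction.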

Other observations

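The lists shown, the correlations, and the Zfp and LPS 18 h replicate 2 patterns with their tests were picked after results were seen; outcomes for and against an explanation were written before its test was run. Of the MHC class I and immunoproteasome list 18 of 18 genes rose after LPS for 18 h, on both adjustments, with H2-Q7 (7.06 ± 0.15), H2-Q6 (6.68 ± 0.18), H2-T22 (4.34 ± 0.10) and H2-Q4 (3.82 ± 0.11) ahead. Adjusted p was 3.8e-14, and 0.039 with an estimated correlation. Cytokine and chemokine genes were still raised, 23 of 26 with adjusted p = 6.7e-13 (0.0034 with an estimated correlation), as were Cxcl3 (at least 407-fold higher), Ccl5 (10.90 ± 0.18), Il1b (9.99 ± 0.32) and Il1a (9.78 ± 0.20). Of 13 itaconate and arginine metabolism genes 9 rose and 3 fell, 9 and 4 adjusted over the list alone (adjusted p = 0.0042, and 0.039 with an estimated correlation), with Acod1 (10.73 ± 0.22), Arg1 (8.45 ± 0.23) and Ass1 (6.40 ± 0.13) higher; with library-size scaling 7 rose and 4 fell.

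Of cholesterol synthesis genes 16 of 23 fell and 3 rose under LPS with IFNg at 18 h (adjusted p = 0.0028, and 0.11 with an estimated correlation), among them Stard4 (-3.95 ± 0.17), and with library-size scaling 19 fell and 2 rose. IL-4 at 18 h raised 23 of 25 ribosomal protein genes, 25 adjusted over the list alone, by small amounts such as 0.53 ± 0.09 for Rps18. The list had adjusted p = 1.6e-06, and 0.49 with an estimated correlation; without LPS 18 h replicate 2 and IL-4 18 h replicate 2, 20 rose and the median fell from 0.33 to 0.21.

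Zinc finger genes with Zfp symbols fell 1 h after LPS: of 301 tested, 153 fell and 15 rose, and with IFNg added 186 fell and 19 rose, while under IL-4 at 1 h 2 fell and 16 rose, and under LPS at 18 h 43 fell and 59 rose. Their median of -0.67 lay below the -0.11 to -0.01 that held the central 95% of 10000 lists matched on GC content, exon length and expression level, which excluded these properties as the whole cause. Reads shared between neighbouring Zfp genes were excluded as the whole cause too, since the 107 with no other tested Zfp gene within 500 kb had a median of -0.38, against -0.12 to 0.02 in their matched lists. A candidate explanation is that these transcripts are short-lived and their synthesis paused, which was not tested, since the sources hold no half-lives.

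LPS 18 h replicate 2 stood apart from the other replicates of its group. Its deviation had r = 0.0482 across 9526 genes with the 18 h response to LPS with IFNg. Unstimulated 1 h replicate 3 had 0.246, so r cannot settle a stronger or weaker response. GC content and exon length explained 25.6% of the variance of its deviation, just past the 25% set beforehand, against 18.2% in IL-4 18 h replicate 2 and at most 6.71% in libraries outside these 2 groups, so a bias in library preparation or RNA quality may account for part of it. RNA from another cell type stayed open, as the highest median deviation of a marker list was 0.56, for 3 mast cell and basophil genes, between the bounds of 0.5 and 1 set for it; no biological explanation was tested. Its deviation correlated with that of IL-4 18 h replicate 2 (r = 0.607).

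At 1 h the deviation of replicate 3 in each of the 4 groups had r of 0.227 to 0.269 across genes with the 18 h response to LPS with IFNg, and that of replicate 2 had r of -0.190 or lower.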
